A study of Arabidopsis thaliana with 18 samples.

How the data were processed

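RNA from whole Arabidopsis thaliana seedlings, 7 days old, was measured on 18 Affymetrix arrays. Seedlings of 3 genotypes, the wild type Col-0 and the mutants sav3-2 and sav1-1, were grown at 22 °C in simulated continuous white light made of red light at 13 and blue light at 1.23 µmol m-2 s-1. Arrays labelled Wc were made from seedlings kept in that light, and arrays labelled SH from seedlings given 1 h of simulated shade, a low ratio of red to far-red light (R:FR of 0.7, with far-red light at 20.2 µmol m-2 s-1). Each of the 6 groups held 3 arrays, which the labels describe as independent biological replicates. Groups and replicate numbers were taken from the sample titles.

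The authors deposited 1 linear intensity value per probe set and array, in a table of 22810 probe sets, all of which are positive. Per the submitters' processing notes GCRMA was named as a tool, with no version. The deposited intensity values are on a linear scale and their medians differ between arrays, from 34.4 to 65.6, so they were treated as not yet brought to a common scale; how GCRMA was applied is not given in the sources used here. The analysis plan, written before the data were examined, foresaw the deposited values as they stand as the main setting and quantile normalization as an alternative. After the array medians had been seen, and before any test was run, quantile normalization was made the main setting, and the values as deposited became an added alternative. Changes in total RNA content that move most genes one way cannot be seen after quantile normalization.

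The 64 control probe sets were left out, values were quantile normalized, and probe sets were kept if the log2 intensity was above 4 on at least 3 of the 18 arrays, which left 17125 of 22746. Tests used log2(value + 16), so fold changes are on that scale and understate the change of dim genes. The table used here holds no detection calls, and the number of arrays limits the precision. A group means model over all 18 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that the 6 groups share 1 estimate of the spread. There were 10 comparisons, namely low R:FR against white light in each genotype, each mutant against Col-0 in each light, and the differences in shade response between genotypes as interaction contrasts. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested in that comparison. All tests were two-sided. Standard errors (SE) use the moderated variance of eBayes, and standard deviations (SD) are over the 3 arrays of a group.

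Gene names came from the platform's annotation, updated through a gene table of the TAIR10.1 assembly that was used for names only. Of the 22746 probe sets, 13513 name 1 gene, 503 name several and 8730 are unnamed here; 13484 of the first matched the gene table. No probe set naming several genes was used to name a gene, and a gene on several probe sets was represented in lists by the brightest. No probe set used here names TAA1, the gene known as SAV3, so the targeted gene was not analysed here and does not check the labels; the gene affected in sav1-1 is not given in the sources used here. No genome coordinates are given, since no build is named for the arrays.

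Genes were named by a rule set before the data were examined. In each comparison these were the 10 called probe sets with the largest positive and the 10 with the largest negative change that name 1 gene and whose arrays do not overlap between the groups, a condition not asked of the differences in shade response. TAA1 and members of the gene lists were to be named as well, and 20 lists were fixed at the same time. The lists cover shade markers, Aux/IAA, GH3, SAUR, auxin biosynthesis, auxin transport, brassinosteroid biosynthesis, brassinosteroid-induced, gibberellin, expansin and XTH, photosynthesis, flavonoid, circadian clock, ethylene, cytokinin, photoreceptor and PIF, root markers, seed storage, abiotic stress, and defence and jasmonate genes. Because few of their members are named by a probe set, 22 families defined by name patterns were added after the annotation had been seen and before any test. The 28 lists of 42 with at least 3 measured members were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those 28 within a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance.

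The size of the shade response was compared in a pair of genotypes over the probe sets called in the remaining genotype, so that selection did not favour either side. Replicate numbers were taken to pair the arrays of a comparison where the deviations from group means of all 3 same-numbered pairs correlated above 0.1. The numbers come from the sample titles, and the labels do not say that they mark a shared day. The lowest correlation was 0.105 for the shade response in sav3-2, 0.108 for sav1-1, 0.105 and 0.101 for sav3-2 against Col-0 in white light and low R:FR, and 0.163 for sav1-1 against Col-0 in white light, which count as paired. It stayed under the limit in the remaining 5 comparisons, for example 0.0714 for the shade response in Col-0, which does not show that the numbers are unrelated there. The main fit holds no block for the number in any comparison, including those that count as paired. A fit with the block is among the alternatives.

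Alternatives covered the filter (none, or log2 of 6), pseudocounts of 1 and 32, median scaling, the variance model, array weights, the replicate number as a block, probe sets naming 1 gene, a minimum of 2-fold, fits to the groups of the comparison alone, each array left out in turn, and, added after the data had been seen, no normalization and leaving out all arrays numbered 3. The response sizes were computed over the probe sets each alternative called and, added after the data had been seen, over those called in the main setting. The limma fit was tested on simulated data over 17125 probe sets with 200 changed. These data held independent normal noise, with no correlation between genes and no effect of the replicate number. Normalization, the filter and the pseudocount were not tested, so these rates need not hold for the real arrays. For the shade response in Col-0 the fit recovered 92% of 100 probe sets changed by 1 on the log2 scale. It recovered 99% of 100 changed by 2, with 6 false among 197 calls. For the difference in shade response between sav3-2 and Col-0 it recovered 63% and 98%, with 12 false among 173 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.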

Results

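The arrays compared gene expression in the wild type and a pair of mutants with and without 1 h of low R:FR light, to find how the mutants' responses to shade differ from that of the wild type. Low R:FR is the light signal by which plants detect neighbours, and SAV3, also known as TAA1, is an enzyme of auxin synthesis. Each of the 6 groups had 3 arrays. Median intensities lay between 34.4 and 65.6 per array before normalization. Within groups, arrays correlated with r from 0.973 to 0.987 across probe sets. The first 3 principal components held 19.8%, 12.3% and 9.8% of the variance, and on the second the arrays numbered 3 lay apart from most others in every group. The arrays of the compared groups did not overlap for between 11.4% and 15.3% of probe sets, where chance gives 10%.

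In Col-0, low R:FR raised all measured shade markers and some of the measured Aux/IAA and GH3 genes, where measured means named by a kept probe set. Most markers on the list, among them ATHB2, PIL1 and HFR1, were not measured in this sense, so nothing is said of them. IAA29, an Aux/IAA repressor of auxin signalling, rose by 3.38 on the log2 scale (SE 0.35, limma adjusted p = 2.19e-06). HAT2, a homeodomain leucine zipper factor, rose by 2.17 (SE 0.13, adjusted p = 1.16e-09), from 8.03 ± 0.14 to 10.20 ± 0.10 (SD, n = 3), and GH3.3, which conjugates auxin to amino acids, by 1.77 (SE 0.14, adjusted p = 4.43e-08). AT2G18010, the auxin-induced SAUR10, rose by 1.81 (SE 0.20). Its white light mean of 4.26 lies close to the lower end of this scale, and the rise ran from 1.24 to 3.80 over the alternative settings. Other large increases among named genes were those of AT4G27280 (2.22), AT5G62280 (2.17), AT5G12050 (2.15), AT5G66590 (1.93), AT3G50340 (1.74) and AT1G69570 (1.67). Decreases were smaller, with AT1G78170 at -1.07, AT1G51805 at -0.96, AT1G74940 at -0.86, AT1G15260 at -0.67, AT1G54820 at -0.64 and AT5G06270 at -0.63. AT3G44450 (-0.86), AT4G24780 (-0.79), AT1G34420 (-0.78) and AT1G77280 (-0.68) were called too, in calls lost in 4, 1, 6 and 3 of 6 fits that left out 1 array. YUC2, a flavin monooxygenase of auxin synthesis, rose by 0.77 (SE 0.12), and WES1, also called GH3.5, by 0.96 (SE 0.14). BZIP61 (1.22) and WRKY22 (1.34), transcription factors, rose too.

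By list, all 3 measured shade markers rose in Col-0 (HAT2, IAA29 and XTH33; camera adjusted p = 7.77e-17, and 4.22e-05 with an estimated correlation). Of 4 measured Aux/IAA genes 2 rose, IAA29 and IAA30 (0.71), while IAA18 stood at -0.33 and IAA34 at 0.33 (list adjusted p = 0.00119, and 0.0216 with an estimated correlation). Of 5 GH3 genes 2 rose and GH3.17, GH3.1 and GH3.9 stood at 0.57, 0.43 and 0.06 (adjusted p = 1.19e-09, and 0.00651 with an estimated correlation). Adjusted over the list alone, 3 shade markers, 2 Aux/IAA and 3 GH3 genes were higher, and 1 Aux/IAA gene was lower. IAA29 is on both the shade marker and Aux/IAA lists, and XTH33 on both the shade marker and the expansin and XTH lists. Results of these lists therefore overlap, here and in the comparisons below. Of 12 expansin and XTH genes 1 rose, XTH33 by 1.01, and the list's adjusted p was 0.0207 (0.0489 with an estimated correlation); 2 were higher adjusted over the list alone. Its median was 0.11, and -0.0333 without normalization between arrays, where the median of all probe sets moved by -0.16 and the list still passed (adjusted p = 0.013).

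In all, limma called 161 probe sets higher and 30 lower in Col-0 of 17125 tested, and 84 and 2 of them changed at least 2-fold. Of the 191 calls 109 are on unnamed probe sets, so the genes named above cover only part of the response. With the replicate number as a block there were 356 calls. Without normalization between arrays the counts were 76 and 9. There the calls of YUC2 (0.63, SE 0.24, adjusted p = 0.698), WES1 (0.78, SE 0.28, adjusted p = 0.534), XTH33 (0.87, SE 0.24, adjusted p = 0.0924), AT1G15260 (-0.84, SE 0.28, adjusted p = 0.357), AT1G54820 (-0.82, SE 0.27, adjusted p = 0.352) and AT5G06270 (-0.81, SE 0.28, adjusted p = 0.403) ended, as the SE rose from between 0.11 and 0.19. None of these calls was lost when 1 array was left out, and that of XTH33 was lost without the arrays numbered 3. The call of IAA30 was lost in 5 of 6 fits that left out 1 array.

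**Figure D1:**
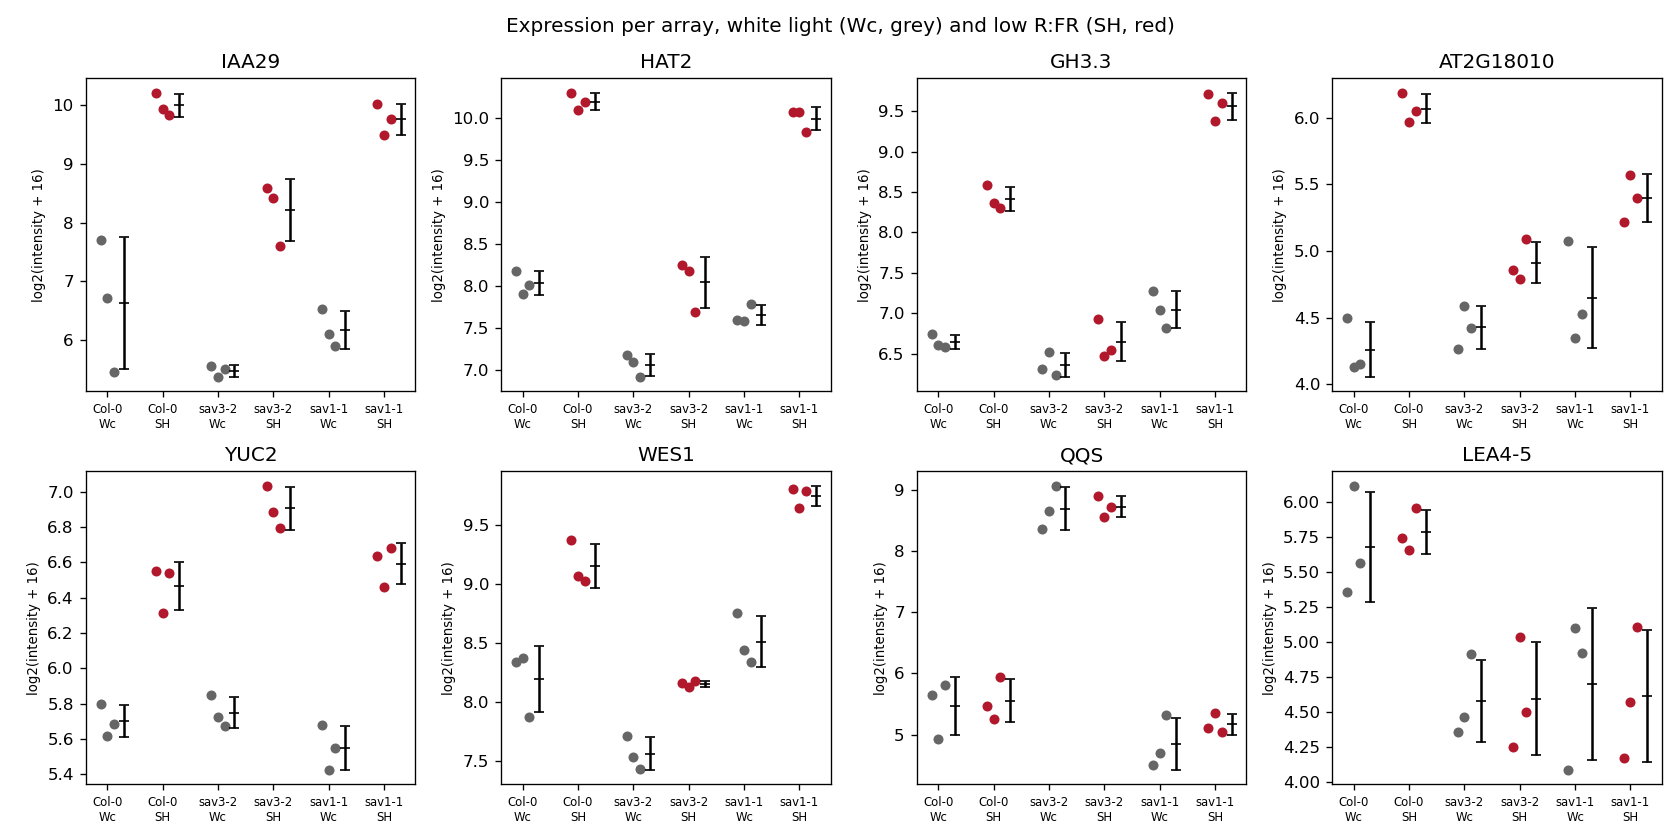
Normalized expression, log2(intensity + 16), of IAA29, HAT2, GH3.3, AT2G18010, YUC2, WES1, QQS and LEA4-5 in the 6 groups; dots are arrays, and the bar beside them is the mean ± SD of 3. GH3.3 rose from 6.64 to 8.42 in Col-0 and from 7.04 to 9.56 in sav1-1, and stood at 6.36 and 6.65 in sav3-2.

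In sav3-2, which is mutated in an auxin synthesis gene, IAA29 rose by 2.74 (SE 0.35, limma adjusted p = 7.32e-05), AT5G12050 by 2.51, AT5G02540 by 2.16, BIM1 of brassinosteroid signalling by 1.65 and WRKY22 by 1.49. HAT2 rose by 0.98 (SE 0.13, adjusted p = 0.000193). YUC2 rose by 1.16 (SE 0.12, adjusted p = 9.09e-06), from 5.75 ± 0.09 to 6.91 ± 0.12 (SD, n = 3). AT5G02580 (1.46), AT5G62280 (1.29), AT3G58640 (1.26) and AT2G28400 (1.26) also rose, and AT3G22970 fell by 0.78 (SE 0.14), a call that ended without normalization (-0.65, SE 0.26, adjusted p = 0.965). AT5G66590 (1.47), AT1G51805 (-0.78), AT2G19650 (-0.68), AT5G03380 (-0.65), AT5G54130 (-0.64), AT1G77280 (-0.61), AT1G74940 (-0.61), AT5G59540 (-0.61), AT3G13120 (-0.52) and AT1G15260 (-0.51) were called, but lost in 3, 1, 4, 5, 5, 6, 3, 4, 5 and 4 of 6 fits that left out 1 array. GH3.3 stood at 0.29 (SE 0.14, adjusted p = 0.604), AT2G18010 at 0.49 (SE 0.20, adjusted p = 0.474) and XTH33 at 0.43 (SE 0.19, adjusted p = 0.522), none of which passed the test. WES1 was called at 0.59 (SE 0.14, adjusted p = 0.0394) but was lost in 5 of 6 fits that left out 1 array.

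Of the 3 measured shade markers 2 rose in sav3-2 (camera adjusted p = 1.73e-08, and 0.00119 with an estimated correlation), and 3 adjusted over the list alone. Of 4 Aux/IAA genes 1 rose, IAA29, and 2 did adjusted over the list alone (list adjusted p = 0.0232); its adjusted p was 0.108 with an estimated correlation. Of 5 GH3 genes 1 was called, also adjusted over the list alone, and the list did not pass (adjusted p = 0.138). The expansin and XTH list did not pass either (0 of 12 called, 1 adjusted over the list alone, adjusted p = 0.577). In all, 108 probe sets were higher and 30 lower, and 78 of these 138 are unnamed. With the replicate number as a block the counts were 196 and 81, and without normalization 78 and 1. The total of 138 calls fell to 67 without sav3-2 SH replicate 1, to 74 without sav3-2 SH replicate 2 and to 91 without sav3-2 Wc replicate 2.

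In sav1-1, IAA29 rose by 3.59 (SE 0.35, limma adjusted p = 7.47e-07), AT5G62280 by 2.89, GH3.3 by 2.52 (SE 0.14, adjusted p = 1.32e-10), HAT2 by 2.34 (SE 0.13, adjusted p = 1.32e-10) and AT5G02540 by 2.18. EXLA1 and EXLA2, expansin-like proteins, rose by 2.12 (SE 0.24) and 1.83 (SE 0.14). AT5G12050 (2.13), AT1G69570 (1.91), AT5G66590 (1.85), WES1 (1.24), YUC2 (1.04) and XTH33 (1.13) rose as well. AT1G51805 fell (SE 0.14, adjusted p = 3.78e-05), AT3G44450 fell by 1.12, AT1G11700 fell by 0.95, AT1G74940 fell by 0.87 and AT4G33960 fell by 0.79; the calls of these last ended without normalization (-0.80 and -0.71, adjusted p = 0.172 and 0.533). AT1G28600 (-1.05), AT5G24570 (-0.93), AT5G55620 (-0.80), TINY2 (-0.80) and AT2G17300 (-0.76) were called, but lost in 4, 3, 4, 5 and 4 of 6 fits that left out 1 array. AT2G18010 stood at 0.75 (SE 0.20, adjusted p = 0.0629).

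All 3 measured shade markers rose in sav1-1 (camera adjusted p = 2.32e-16, and 4.47e-05 with an estimated correlation). Of 4 Aux/IAA genes 2 rose (adjusted p = 0.00309, and 0.0337 with an estimated correlation), and of 5 GH3 genes 3 rose (adjusted p = 1.04e-08, and 0.00987 with an estimated correlation). Of these the calls of IAA30 and GH3.17 were lost in 4 and 3 of 6 fits that left out 1 array. Adjusted over the list alone, 3, 2 and 3 of these were higher and 1 Aux/IAA gene was lower. The expansin and XTH list did not pass (1 of 12 called, 2 adjusted over the list alone, adjusted p = 0.0679). In all, 236 probe sets were higher and 80 lower, and 174 of these 316 are unnamed. The counts were 337 and 163 with the replicate number as a block, and 138 and 7 without normalization. The total of 316 fell to 190 without sav1-1 SH replicate 1.

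The 3 shade responses rest on separate arrays but share 1 estimate of the spread per probe set. Their calls are therefore not independent, and the numbers expected of independent lists are a rough guide only. Of the probe sets higher in Col-0, 82 were also called higher in sav3-2, where 1.02 are the number expected of independent lists, and 145 in sav1-1, against 2.22. In sav3-2 and sav1-1 93 were shared, against 1.49. Between Col-0 and sav3-2 10 lower probe sets were shared, between Col-0 and sav1-1 24, and between sav3-2 and sav1-1 17. Across all 3 genotypes 82 were called higher, among them IAA29, HAT2, YUC2, WRKY22 and BZIP61, and 9 lower, among them AT1G51805 and AT1G74940.

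**Figure D2:**
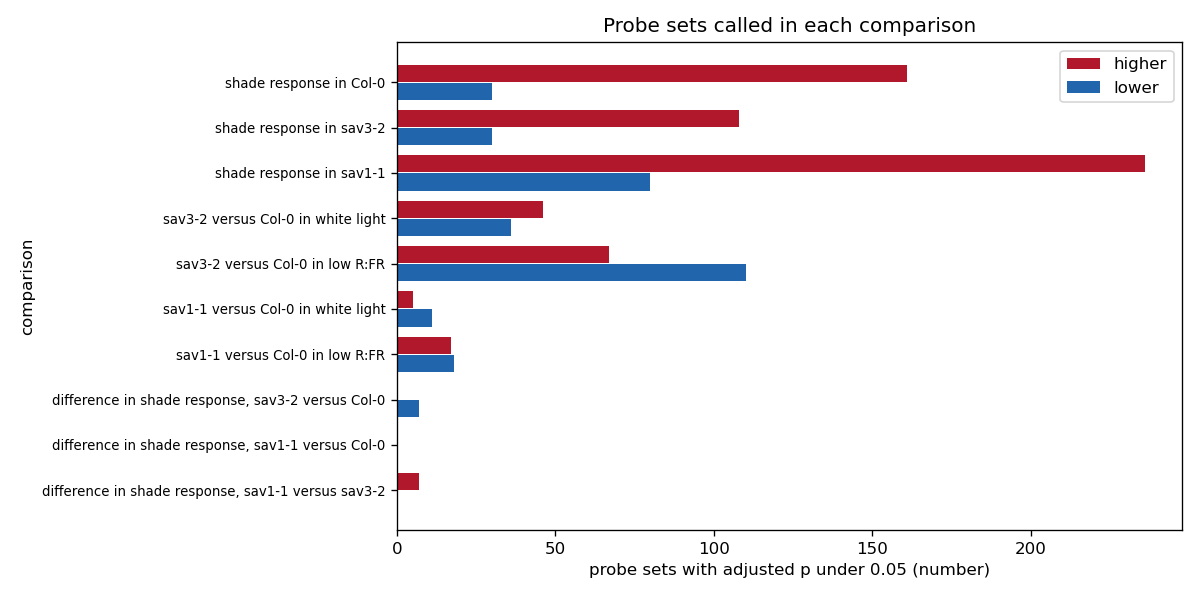
Number of probe sets with a limma adjusted p under 0.05 in each of the 10 comparisons, on an axis that starts at 0; red bars are probe sets higher and blue bars probe sets lower. Low R:FR gave 161 higher and 30 lower in Col-0, 108 and 30 in sav3-2, and 236 and 80 in sav1-1, while the differences in shade response gave 7, 0 and 7 calls.

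The interaction contrasts tested whether the response to low R:FR itself differed. Compared with Col-0, the rise in sav3-2 was smaller for GH3.3 (difference -1.48, SE 0.20, limma adjusted p = 0.00147), HAT2 (-1.19, SE 0.19, adjusted p = 0.0102) and AT3G50340 (-1.04, SE 0.18, adjusted p = 0.0234). Compared with sav3-2, the rise in sav1-1 was larger for GH3.3 (2.23, SE 0.20, adjusted p = 4.63e-06), HAT2 (1.35, SE 0.19, adjusted p = 0.00121) and EXLA2 (1.18, SE 0.20, adjusted p = 0.0149). Both sets of differences use the sav3-2 arrays. The shade marker list differed in the first (camera adjusted p = 2.12e-05, and 0.0114 with an estimated correlation) and in the second (1.37e-07, and 0.0024), as did the GH3 list (7.77e-06, and 0.0446 with an estimated correlation; then 7.16e-08, and 0.0175). In either contrast 1 gene was called in each list, HAT2 among the shade markers and GH3.3 among the GH3 genes. Both are given above, so the results of these short lists are not separate evidence. Adjusted over the list alone, 1 of the shade markers and 1 GH3 gene were called in the first contrast and 2 of each in the second.

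In the first contrast 7 probe sets were called, all lower, and 682 had an unadjusted p under 0.05. In the second 7 were called, all higher, and 533 did. In each contrast 4 of the 7 are unnamed. The mean difference over the first 7 was -1.75, further from 0 than that of each of the 3 named. For sav1-1 against Col-0 limma called 0, with 431 at an unadjusted p under 0.05, and 2 without the arrays numbered 3. Array weights gave 12 calls in the first contrast and 12 in the second. Of 100 groupings of the arrays, the real one included, 13 gave at least as many calls in the first contrast and 9 in the second. Of those that did not turn the genotypes in 1 light alone, 2 of 49 and 3 of 52 others did. These can still hold part of the genotype difference shared by both lights, and part of the real difference in response. They do not measure chance alone, so chance stays open for these counts. The first count was 4 without Col-0 Wc replicate 2, where HAT2 had an adjusted p of 0.0602. It was 2 with a pseudocount of 1, and 3 without normalization. There GH3.3, HAT2 and AT3G50340 stood at -1.19 (SE 0.38), -0.87 (SE 0.39) and -0.77 (SE 0.36), and all had an adjusted p of 0.855, because the SE rose from 0.20, 0.19 and 0.18 while the differences also shrank. AT3G50340 was lost in 8 of 12 fits that left out 1 array and EXLA2 in 6 of 12. The second contrast gave 6 calls without normalization, where HAT2 and EXLA2 were lost at an adjusted p of 0.99999 because the SE rose to 0.39 and 0.35; EXLA2 stayed at 1.14, and HAT2 was at least 1.18 in every setting.

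Over the 236 probe sets higher in sav1-1, the median response was 0.75 in Col-0 and 0.57 in sav3-2, with a median difference of -0.16 (camera p = 8.62e-12, and 0.00378 with an estimated correlation). Without normalization the median over the same 236 was 0.14 and that of all probe sets 0.27. The set thus still lay below the rest (camera p = 8.10e-12 with the preset correlation). Its median difference was above 0 there, on values not brought to a common scale. With median scaling the median difference kept its direction over the probe sets called there. Over the same 236 it was -0.16 with the replicate number as a block and -0.13 without the arrays numbered 3. Over the probe sets that each setting itself called higher in sav1-1 it was -0.000546 (138 probe sets), -0.0784 (337) and -0.0740 (237) in the same order. Over the 108 higher in sav3-2, the medians were 1.00 in Col-0 and 1.15 in sav1-1 (difference 0.18, p = 1.45e-09, and 0.0384 with an estimated correlation), and over the same 108 the difference ran from 0.11 without Col-0 SH replicate 3 to 0.26 without Col-0 SH replicate 1. Over the 161 higher in Col-0, they were 0.68 in sav3-2 and 1.12 in sav1-1 (difference 0.37, p = 6.32e-41, and 8.96e-05 with an estimated correlation). For the probe sets that fell, the medians were -0.46 in Col-0 and -0.42 in sav3-2 over the 80 lower in sav1-1, -0.42 in Col-0 and -0.58 in sav1-1 over the 30 lower in sav3-2, and -0.45 in sav3-2 and -0.66 in sav1-1 over the 30 lower in Col-0. Their differences were 0.08 (camera p = 0.0081, and 0.0505 with an estimated correlation), -0.12 (0.00799, and 0.0116) and -0.20 (1.31e-07, and 6.25e-05). Over the same 80 the camera call on the first was lost without Col-0 SH replicate 1 (median difference 0.0559), sav3-2 Wc replicate 3 (median difference 0.0583) or sav3-2 SH replicate 3 (median difference 0.0313). It was also lost without all arrays numbered 3 (median difference 0.0697). Over the same 30 the call on the second was lost in no fit that left out 1 array, but over the 12 of them that name 1 gene (-0.0792), without all arrays numbered 3 (-0.0456) and without normalization, where the median was 0.13 and that of all probe sets 0.22. Where each fit called its own probe sets, the first was lost without sav1-1 Wc replicate 2 (0.0875 over 42), sav3-2 Wc replicate 3 (0.0448 over 85) or sav3-2 SH replicate 3 (0.0331 over 79), and the second without sav3-2 Wc replicate 1 (-0.0404 over 16), SH replicate 1 (-0.0770 over 8) or SH replicate 2 (-0.15 over 10). In the fits without sav1-1 Wc replicate 2 and those of the second, the array left out is in neither genotype compared, so that the probe sets changed and not their differences. Regroupings of the arrays that turn the genotypes in 1 light alone hold the genotype difference shared by both lights. Among the 49 to 56 others drawn, between 3 and 5 gave a median as far from 0. These others can still hold part of that genotype difference, where more arrays keep their genotype in 1 light than in the other. They can also hold part of the real difference in response. They do not measure chance alone, so chance stays open for all 6 differences, and genes are not independent replicates.

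**Figure D3:**
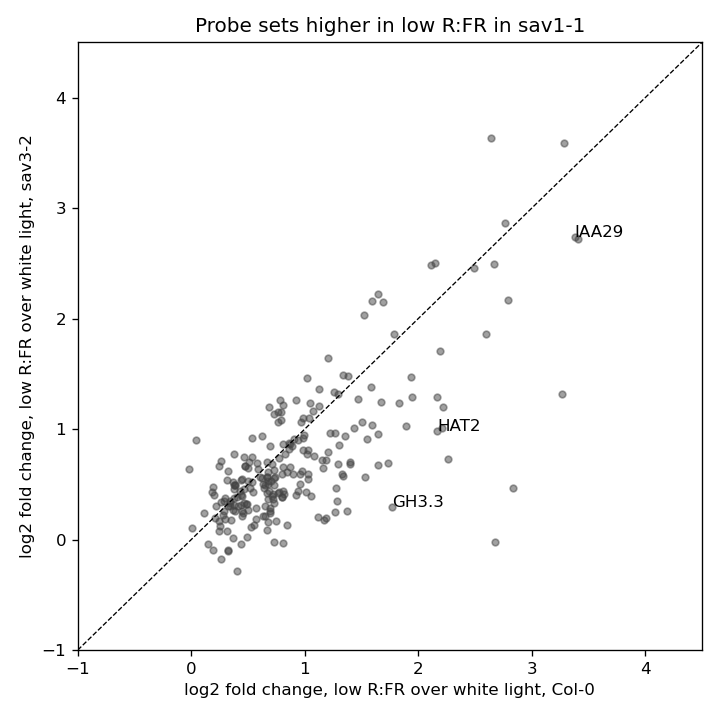
Shade response in Col-0 (horizontal axis) against sav3-2 (vertical axis), both as log2 fold changes, for the 236 probe sets called higher in sav1-1; each point is a probe set and the dashed line marks equal responses. Of these 69.1% lie below the line, with medians of 0.75 in Col-0 and 0.57 in sav3-2.

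Between sav3-2 and Col-0 in white light, the largest difference among named genes was in QQS, a gene known to affect leaf starch. It was 3.23 higher in sav3-2 on the log2 scale (SE 0.23, limma adjusted p = 7.97e-08), at 8.69 ± 0.36 against 5.46 ± 0.47 (SD, n = 3). AT1G19960 was 1.99 higher, AT2G25510 1.96, AT5G24240 1.44 and AT1G35710 1.31. AT5G24240 was dim in Col-0 (mean 4.22), and its difference ran from 0.94 to 3.33 over the alternative settings. HAT2 was lower (-0.97, SE 0.13, adjusted p = 0.000348), as were AT5G62280 (-1.52; adjusted p = 0.0548 in a fit to the compared groups alone) and AT5G13980 (-1.01). BHLH101, a factor induced by iron deficiency, was called at 1.21 and LEA18, a late embryogenesis abundant protein, at -0.91, but these were lost in 4 and 3 of 6 fits that left out 1 array. So were AT5G03350 (1.80), AT2G41090 (1.78), AT1G47400 (1.60), AT5G55450 (adjusted p = 0.0403), AT3G02480 (-1.54), BGLU19 (-1.11), AT5G44440 (-0.97), AtLEA4-1 (-0.95), AT5G12940 (-0.83) and AT1G12080 (-0.78), in 3, 1, 5, 4, 4, 4, 4, 4, 5 and 3 of 6. The shade marker list was lower (1 of 3 called, 2 adjusted over the list alone; camera adjusted p = 0.00177, and 0.0458 with an estimated correlation). Of 5 GH3 genes 1 was called, WES1 at -0.63, a call lost in 4 of 6 such fits, and the list did not pass (adjusted p = 0.0705).

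In all, 46 probe sets were higher and 36 lower in sav3-2, and 38 of these 82 are unnamed. The counts were 90 and 117 with the replicate number as a block, and 27 and 19 without normalization. The total of 82 fell to 40 without Col-0 Wc replicate 1, 38 without Col-0 Wc replicate 2, 49 without sav3-2 Wc replicate 1 and 44 without sav3-2 Wc replicate 2.

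After low R:FR, QQS was higher in sav3-2, at 8.72 ± 0.17 against 5.55 ± 0.35 (SD, n = 3; SE of the difference 0.23, limma adjusted p = 3.76e-08). AT2G25510 was higher by 2.30, AT2G41090 1.85, AT1G19960 1.84 and AT5G24240 1.26 (0.83 to 2.77 over the alternative settings). The listed auxin and shade genes HAT2 (-2.16, SE 0.13, adjusted p = 3.80e-09), GH3.3 (-1.77, SE 0.14, adjusted p = 1.17e-07) and AT2G18010 (-1.16; adjusted p = 0.134 with a pseudocount of 1, at -1.80) were lower. So were AT5G62280 (-2.39), AT3G50340 (-1.43), AT5G44440 (-1.35) and AT5G41400 (-1.34), which are in none of the lists. AT5G44440 was dim in sav3-2 (mean 4.18), and its difference ran from -3.41 to -0.86 over the alternative settings. IAA29 was called at -1.79 (SE 0.35, adjusted p = 0.00809), with adjusted p = 0.0511 without Col-0 SH replicate 1 and 0.0601 without sav3-2 SH replicate 3. AT5G03350 (1.73), AT1G47400 (1.42), AT2G32160 (1.39), AT3G05170 (adjusted p = 0.0162), AT5G24210 (1.17), LEA4-5 (-1.19) and P1R3 (-1.18) were called, but lost in 2, 5, 1, 4, 4, 5 and 3 of 6 fits that left out 1 array. The shade marker list was lower (2 of 3 called; camera adjusted p = 1.03e-09, and 0.000781 with an estimated correlation), as was the GH3 list (2 of 5 called, of which WES1 had an adjusted p of 0.422 without normalization; adjusted p = 1.03e-09, and 0.00634 with an estimated correlation). The Aux/IAA list had 1 of 4 called and an adjusted p of 0.0323, or adjusted p = 0.105 with an estimated correlation. The expansin and XTH list had 0 of 12 called and an adjusted p of 0.0398, or adjusted p = 0.0947 with an estimated correlation, and its median was -0.19. Without normalization that median was 0.0147 with an adjusted p of 0.0507, where the median of all probe sets moved by 0.17. Adjusted over the list alone, 3, 4, 2 and 2 genes of these lists were lower.

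In all, 67 probe sets were higher and 110 lower, and 101 of these 177 are unnamed. The counts were 172 and 225 with the replicate number as a block, and 47 and 36 without normalization. The total of 177 fell to 115 without Col-0 SH replicate 1, 113 without Col-0 SH replicate 2, 100 without sav3-2 SH replicate 1 and 111 without sav3-2 SH replicate 2.

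Between sav1-1 and Col-0 in white light, AT4G27280 was higher in sav1-1 (1.37, SE 0.17, limma adjusted p = 0.00133) and AT4G14100 was lower (-1.02, SE 0.14, adjusted p = 0.00133), a call that ended without normalization (-1.01, SE 0.25, adjusted p = 0.0885). AtLEA4-1 and LEA18, late embryogenesis abundant proteins, were called at -1.03 (adjusted p = 0.0466) and -0.99 (adjusted p = 0.0152), AT1G12080 at -0.88 and AT4G21870 at 0.73, and these calls were lost in 5, 3, 4 and 4 of 6 fits that left out 1 array. No list passed; the shade markers had an adjusted p of 0.0922. In all, 5 probe sets were higher and 11 lower, and 10 of these 16 are unnamed. The counts were 28 and 64 with the replicate number as a block, and 3 and 4 without normalization. The total was 113 with array weights and 67 without the arrays numbered 3. The total of 16 became 5 without Col-0 Wc replicate 1, 8 without Col-0 Wc replicate 2, 45 without Col-0 Wc replicate 3, 8 without sav1-1 Wc replicate 2 and 5 without sav1-1 Wc replicate 3.

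After low R:FR, GH3.3 was higher in sav1-1 than in Col-0 (1.15, SE 0.14, limma adjusted p = 0.000373), at 9.56 ± 0.17 against 8.42 ± 0.15 (SD, n = 3), and AT4G14100 was lower (-0.94, SE 0.14, adjusted p = 0.00352), a call that also ended without normalization (-0.69, SE 0.25, adjusted p = 0.481). STZ, a zinc finger factor of salt stress, was called at 1.40 and AT3G49960 at 1.42, calls lost in 3 and 5 of 6 fits that left out 1 array. AT3G02480 at -1.55 was lost in 6 of 6, AT5G44440 at -1.19 in 3 and LEA18 at -0.85 in 4. AT1G32920 (0.88), AT2G38870 (0.83), AT3G16670 (0.77), AT4G21870 (0.72), AT4G23680 (-1.05), AT4G29270 (-0.95), AT4G18970 (-0.94), AT3G48970 (-0.85), AT1G67050 (-0.79) and AT5G61660 (-0.75) were lost in 4, 5, 6, 4, 5, 6, 5, 4, 5 and 2. Of 5 GH3 genes 1 was called, 2 adjusted over the list alone, and the list's adjusted p was 0.022, or adjusted p = 0.326 with an estimated correlation. In all, 17 probe sets were higher and 18 lower, and 15 of these 35 are unnamed. The counts were 78 and 78 with the replicate number as a block, 52 and 42 with array weights, 34 and 32 without the arrays numbered 3, and 38 and 8 without normalization. The total of 35 became 15 without Col-0 SH replicate 1, 7 without Col-0 SH replicate 2, 61 without Col-0 SH replicate 3, 7 without sav1-1 SH replicate 1, 12 without sav1-1 SH replicate 2 and 10 without sav1-1 SH replicate 3.

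The remaining fixed lists gave few or no calls. Of the auxin biosynthesis genes 2 were measured, YUC2 and YUC6, and YUC6 stood at -0.20 in the Col-0 shade response; of the SAUR genes only AT2G18010 was measured. The single measured genes of auxin transport (WAG2), the brassinosteroid-induced list (EXPA8), the circadian clock (GI) and defence and jasmonate (PDF1.2) stood at 0.14, 0.45, 0.03 and 0.59 in the Col-0 shade response and were not called in any comparison. Neither were the 2 photosynthesis genes (LHCB4.1 at -0.05 and LHCB4.2 at -0.02), the 2 cytokinin genes (ARR15 at 0.22 and RR16 at 0.18) or the 2 abiotic stress genes (COR47 at -0.10 and COR15A at -0.44). The 3 root markers (camera adjusted p = 0.846 in that response), the 3 flavonoid genes (0.467) and the 3 gibberellin genes (0.544) gave no calls either. Adjusted over the list alone, which for a list with 1 measured gene leaves the p unadjusted, some of these had a p under 0.05 without passing over all probe sets. For AT2G18010 this was so in the shade responses of sav3-2 and sav1-1, in sav1-1 against Col-0 after low R:FR (-0.67, adjusted p = 0.254 over all) and in the differences in shade response from Col-0 of sav3-2 (-1.32, 0.169) and sav1-1 (-1.06, 0.99993). It was so for EXPA8 and the 2 abiotic stress genes in each mutant against Col-0 in both lights (all negative), WAG2 (-0.60) and YUC2 (0.44) in sav3-2 against Col-0 after low R:FR, and PDF1.2 in the Col-0 shade response. The count was 1 flavonoid gene (negative) and 1 cytokinin gene (positive) in the sav1-1 shade response. For gibberellin it was 1 positive and 1 negative in the sav3-2 shade response and 1 positive in sav3-2 against Col-0 after low R:FR. No probe set named a member of the brassinosteroid biosynthesis, ethylene, photoreceptor and PIF or seed storage lists.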

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

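The test of a genotype difference over further shade-responsive probe sets was chosen after the results were seen, as were the seed line test for QQS and the low R:FR test of 3 late embryogenesis abundant genes, given with the other observations, and the fits without normalization and without the arrays numbered 3. The difference itself was tested for each result here, by an interaction contrast in limma.

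The responses of sav3-2 and Col-0 to low R:FR differed for 7 probe sets. Of these 4 are unnamed, and 3 name GH3.3 (-1.48), HAT2 (-1.19) and AT3G50340 (-1.04), each closer to 0 than the mean of the 7 given below. The responses of sav1-1 and sav3-2 differed for 7, of which 4 are unnamed and 3 name GH3.3 (2.23), HAT2 (1.35) and EXLA2 (1.18). Both contrasts use the sav3-2 arrays, so the second is not independent evidence.

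For the first 7 probe sets the mean difference was -1.75 (mean SE 0.25). Compression of dim signals is argued against by a mean of -1.98 with a pseudocount of 1, where calls fell to 2 because the mean SE rose to 0.47. Scaling is argued against by -1.51 without normalization, where calls fell to 3 as the mean SE rose to 0.35. Leaving out the array whose loss shrinks it most gave -1.63. The 7 were picked because they were called on these same arrays. Probe sets that rest on 1 array are seldom called, so this value cannot decide on a single array. Such picking also tends to place the mean of -1.75 too far from 0. A smaller response in sav3-2 that reaches other genes is a candidate explanation: over the 229 further probe sets higher in sav1-1 the median difference was -0.15 (camera p = 0.00974 with an estimated correlation), but 5 of the 49 regroupings that did not turn the genotypes in 1 light alone gave a median as far from 0 over the same 229, with a highest of 0.30. Over all 236 the median was 0.14 without normalization, where that of all probe sets was 0.27, so the set still lay below the rest. All probe sets moved by 0.0023 after quantile normalization and by 0.0143 after median scaling. With median scaling the direction was kept over the probe sets called there. The positive sign goes with the shift of all probe sets on unscaled values. Whether the smaller response reaches other genes stays open. The regroupings can hold part of the genotype difference shared by both lights, and part of the real difference in response. They therefore leave chance open for this median and for the count itself.

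Other groupings of the same arrays were fitted for every count. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each. The real shade response count in Col-0 was 191 and the highest other 1. For sav3-2 and sav1-1 they were 138 and 316, with a highest other of 0. For sav3-2 against Col-0 the real counts were 82 in white light and 177 in low R:FR, and for sav1-1 against Col-0 they were 16 and 35, each with a highest other of 0. In the comparisons whose numbers pair the arrays, the 3 other splits that part as many pairs all gave 0.

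For the differences in shade response 100 groupings were fitted, the real one included, and in the others genotypes were exchanged within each light. For sav3-2 against Col-0, 13 gave at least 7 calls and the highest other gave 386. That grouping turned the genotypes in white light and kept all 6 arrays in low R:FR, so it measures the genotype difference shared by both lights, a structure of the samples. Among the 49 drawn that turned no light in this way, 2 gave as many and the highest gave 9. For sav1-1 against sav3-2, 9 gave at least 7 and the highest other was 35. Of the 8 others among these, 5 turned the genotypes in 1 light, and among the 52 drawn that did not, 3 gave as many and the highest gave 10. Those drawn without such a turn can still hold part of the genotype difference, where more arrays keep their genotype in 1 light than in the other. They can also hold part of the real difference in response. They do not measure chance alone, so chance stays open for either count. For sav1-1 against Col-0 the real count was 0, so all 100 gave as many whatever the data, which tests nothing; the highest other was 194.

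The median differences in response size were compared over 100 groupings too, the real one included. They were as far from 0 in 38 for the probe sets higher in sav1-1 (real -0.16, highest other 0.46). The number was 22 for those lower (0.08, highest other 0.18). The numbers were 13 for those higher in sav3-2 (0.18, highest other 0.34), 18 for those lower (-0.12, highest other 0.24), 10 for those higher in Col-0 (0.37, highest other 0.59) and 9 for those lower (-0.20, highest other 0.33). Many of these groupings turned the genotypes in 1 light alone and so hold the genotype difference shared by both lights, which is not chance. Among the groupings that did not, the numbers were 5 and 3 of 49, 5 and 3 of 56, and 4 and 3 of 52 in the same order. These can still hold part of that genotype difference and of the real difference in response, so chance stays open for all of them.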

How the results depend on the processing

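The fits without normalization and without the arrays numbered 3, the list tests after median scaling, and the sizes over the probe sets of the main setting, were chosen after seeing the data; the others were planned. The balance of higher and lower calls turned for sav3-2 against Col-0 in low R:FR without normalization (47 and 36, from 67 and 110), and in white light with the replicate block (90 and 117, from 46 and 36) and array weights (83 and 87). For sav1-1 in low R:FR it went from 17 and 18 to 38 and 8 without normalization. Median scaling, robust eBayes, the filter at log2 of 6 and a pseudocount of 32 moved none of the counts, or of the response sizes over the probe sets each called, past 1.5 times or the threshold. Quantile normalization, planned as an alternative, is the main setting. Fits to the groups of the comparison alone do not apply to response sizes. The array table gives no background, so what dim signals limit was judged from the pseudocount and filter alone.

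With the replicate number as a block, calls numbered 356 in the shade response of Col-0, 277 in sav3-2 and 500 in sav1-1, 207 and 397 for sav3-2 against Col-0 in white light and low R:FR, 92 and 156 for sav1-1, and 11 for the difference between sav1-1 and sav3-2; it ended none of 164 gene calls and 3 list calls. By the limit of 0.1 the numbers were not taken to pair the arrays for Col-0 shade (lowest r 0.0714), sav1-1 against Col-0 in low R:FR (0.0963) or the differences. Even so, among the arrays of other groups, 17 of 18 arrays correlated best with an array of their own number. The arrays numbered 3 also lay apart on the second principal component. In the data as a whole, arrays of 1 number therefore share an effect, which the main fit leaves in the spread. The labels do not say what the number marks. Because fewer probe sets were tested, those naming 1 gene gave 78, 55, 131, 43, 70, 5, 3 and 3 calls (the 3 shade responses, sav3-2 against Col-0 in white light and low R:FR, sav1-1 in white light, and the differences with sav3-2), and a minimum of 2-fold by its construction gave 86, 56, 112, 32, 66, 6 and, for sav1-1 in low R:FR, 14. For the rest the cause was not tested. Without normalization calls were 85, 79, 145, 46, 83, 7 and, for sav3-2 minus Col-0, 3; median shifts of all probe sets there were -0.16 (Col-0 shade), 0.11 (sav3-2 shade), -0.10 and 0.17 (sav3-2 against Col-0), 0.22 (sav1-1 in low R:FR), and 0.27 and 0.22 (differences from Col-0). Array weights gave 528 (sav1-1 shade), 170 (sav3-2 in white light), 113 and 94 (sav1-1 against Col-0), 12 and 12 (differences). Without the arrays numbered 3 there were 259 (sav3-2 shade), 168, 67, 66 and 2 (sav1-1 minus Col-0). Without the trend there were 53, 10 and 21 (sav3-2 in white light, sav1-1 in both lights); with no filter, 23 for sav1-1 in low R:FR; fitting the compared groups alone, 30, 4 and 4 (both mutants in white light, sav3-2 minus Col-0); with a pseudocount of 1, 2 for sav3-2 minus Col-0.

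Leaving out 1 array at a time gave 137 to 190 calls in Col-0 shade, 67 to 135 in sav3-2, 190 to 266 in sav1-1, 38 to 87 and 100 to 164 for sav3-2 against Col-0, 5 to 45 and 7 to 61 for sav1-1, 4 to 10 for sav3-2 minus Col-0, 6 to 8 for sav1-1 minus sav3-2 and 0 to 0 for sav1-1 minus Col-0. Response sizes over the probe sets each fit called ranged from -0.21 to -0.11, 0.09 to 0.28 and 0.31 to 0.45 for probe sets higher in sav1-1, sav3-2 and Col-0, and from 0.0331 to 0.13, -0.15 to -0.0404 and -0.24 to -0.16 for those lower. Other settings moved sizes past 1.5 times with the call kept, over probe sets called anew in each, so that setting and set changed together. For those higher in sav1-1 (236 in the main setting) these were -0.0784 with the block (337), -0.108 with array weights (343), -0.0740 without the arrays numbered 3 (237) and -0.000546 without normalization (138). For those higher in sav3-2 they were 0.113 with array weights and 0.472 without normalization, and for those higher and lower in Col-0 0.636 and -0.366 without normalization. For those lower in sav1-1 the block gave 0.0493, and for those lower in sav3-2 array weights gave -0.0660 and leaving out the arrays numbered 3 gave -0.05. The call on those lower in sav1-1 ended at 0.0570 with array weights, 0.39 without normalization and 0.0605 without the arrays numbered 3. That on those lower in sav3-2 ended at -0.0331 with no filter, -0.0777 without the trend and -0.10 with 1-gene probe sets; without normalization it had no value. Camera fitted its own intensity trend of the variance in every setting, and used neither the eBayes trend setting nor the array weights. In the setting without the trend, then, the probe sets alone changed. Over the probe sets of the main setting, those higher in sav1-1 gave -0.16 with the block, -0.18 with array weights and -0.13 without the arrays numbered 3, so their smaller sizes above came mostly from the probe sets called. Without normalization, 2 medians changed sign there, those higher in sav1-1 (0.14, where all probe sets moved by 0.27) and lower in sav3-2 (0.13, by 0.22; call ended). Calls ended over these sets for those lower in sav1-1 without the arrays numbered 3 (median difference 0.0697), and for those lower in sav3-2 there (-0.0456) and with 1-gene probe sets (-0.0792, over 12 of 30). With no filter and without the trend, both were kept.

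Of 164 gene calls, 65 were lost without normalization, 40 with the compared groups alone, 34 without the trend, 28 with no filter, 24 without the arrays numbered 3, 18 with a pseudocount of 1 and 16 with robust eBayes; none reversed. Of 1020 gene results without 1 array, 307 were lost. List calls numbered 39 of 280, and 26 with an estimated correlation, 37 with fry, 40 with median scaling and 38 without normalization. There 5 list medians changed sign, where all probe sets moved the same way: expansin and XTH (-0.0333), bZIP factors (-0.00941) and tetraspanins (-0.0187) in Col-0 shade, UDP-glycosyltransferases (0.0217) in sav3-2 shade, and expansin and XTH (0.0147) for sav3-2 against Col-0 in low R:FR. Their adjusted p were 0.013, 0.00108, 0.192, 0.0269 and 0.0507, so 3 still passed.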

Other observations

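The gene families below were defined after the annotation had been seen and before any test; the seed line test for QQS and the low R:FR test of the late embryogenesis abundant genes were chosen after the results were seen, as was the fit without normalization.

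Among the added families, of which some overlap the fixed lists, the 15 named expansins passed with low R:FR in Col-0 (2 called higher, EXLA1 and EXLA2; camera adjusted p = 0.00017, and 0.0115 with an estimated correlation) and in sav1-1 (2 called; 0.00214, and 0.0296). In sav3-2 the same 2 were called, EXLA1 (adjusted p = 0.023) and EXLA2 (0.65, adjusted p = 0.0226), and the family did not pass (0.108). The family was lower in sav3-2 than in Col-0 after low R:FR (0.000701, and 0.0204), with 1 called, EXLA2. That call was lost in 6 of 6 fits that left out 1 array, the calls of EXLA1 and EXLA2 in sav3-2 in 5 of 6 each, and that of EXLA1 in Col-0 in 3 of 6. Of 16 bZIP factors 2 rose in Col-0 and in sav1-1, BZIP61 and BZIP34 (adjusted p = 0.000229 and 0.000498, and 0.0216 and 0.0296 with an estimated correlation). In Col-0 the family also passed without normalization (adjusted p = 0.00108), where its median was -0.00941 and that of all probe sets moved by -0.16. The 15 genes named for auxin, which include the Aux/IAA and GH3 genes, had 7, 4 and 7 called higher in Col-0, sav3-2 and sav1-1. Of 36 UDP-glycosyltransferases 3 fell in sav1-1 (adjusted p = 0.0143), with adjusted p = 0.0627 with an estimated correlation. The calls of GT72B1, UGT72B3 and UGT88A1 behind this were lost in 4, 4 and 3 of 6 fits that left out 1 array. UGT88A1 was also called lower in Col-0 (-0.49, limma adjusted p = 0.00676), a call that ended without normalization (adjusted p = 0.905). The family also passed in the sav3-2 shade response and the tetraspanins in that of Col-0. Without normalization both medians changed sign (0.0217 and -0.0187), and the tetraspanins no longer passed (camera adjusted p = 0.192).

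QQS was higher in sav3-2 than in Col-0 by 3.23 in white light, and was called in low R:FR as well. A single array is argued against by a smallest difference of 2.96 without any 1 array. Its response to light did not separate the genotypes (difference in shade response -0.0582). QQS is known to vary between Arabidopsis lines with its methylation, so a line difference unrelated to the mutation is a candidate explanation. With 1 line per genotype this and an effect of the mutation cannot be told apart.

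LEA4-5, AtLEA4-1 and LEA18, late embryogenesis abundant genes picked after their values were seen, had a mean of -0.99 in white light over the 3 genes and both mutants against Col-0. No list test was made of them. In white light AtLEA4-1 and LEA18 were called in both mutants and LEA4-5 in neither; in low R:FR all 3 were called in sav3-2 and LEA18 in sav1-1. Calls refitted with 1 array left out (both genes in white light, LEA4-5 in sav3-2 and LEA18 in sav1-1 in low R:FR) were lost in 3 to 5 of 6 fits. A single Col-0 array as the whole cause is argued against by a mean of -0.85 without the one whose loss shrinks it most. Both white light comparisons share the Col-0 arrays; the mean was -0.95 in low R:FR, but the genes were partly picked from those values, so chance in the shared arrays stays open. Ungerminated seeds in the Col-0 samples could also account for it; 0 seed storage genes were named by a probe set, so this could not be tested. No biological explanation beyond the genotypes themselves was tested.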
